A study of Mus musculus with 5 samples.

How the data were processed

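Single-cell RNA libraries had been prepared from kidneys of 5 C57BL/6j mice with lupus-like disease induced by pristane, a hydrocarbon oil. Per the labels, 2 mice received saline and 3 received a faecal microbiota transplant (FMT) from MRL/MpJ donors. The labels describe the libraries as 10x Genomics droplet libraries, while the extraction text names a total RNA kit and an mRNA library kit and speaks of epithelial cells and B cells. The matrices hold many immune and epithelial cell types, so cells were classed from their expression. Sample titles carry letter codes that differ between the groups (C and D for saline, B for FMT), and their meaning is not given in the sources used here. A cage, litter or preparation batch that follows those codes could not be separated from the treatment.

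The deposited matrices hold raw UMI counts (unique molecular identifiers) per gene and barcode, and all counts were used as deposited. The submitters' processing notes name Cell Ranger 2.1.1 and the mm10 build, whereas the matrix headers name Cell Ranger 4.0.0, so the version stays open. The gene list of 27998 genes was the same in every library and had 65 repeated symbols, which were kept apart by gene identifier. It holds 0 constant or variable genes of immunoglobulins or T cell receptors, so the planned comparison of immunoglobulin isotypes was not run. Gene coordinates came from GENCODE M21, in which 27645 of the identifiers were found. Each UMI count covers the whole annotated gene.

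The libraries held between 15333445 and 45309178 UMIs in 26237 barcodes. Cells with at least 200 genes and under 50% mitochondrial UMIs were kept, which left 22591. Doublets were scored within each library with Scrublet, as provided by scanpy 1.11.5, and the highest scores, in proportion to the number of cells, were removed, 883 in all, so that 21708 cells were used. Counts were scaled to 10000 per cell and logged, 2000 variable genes were taken over the libraries, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1.0, fixed seed) gave 28 clusters. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Marker lists named the clusters, and those of one type were merged into 12 named classes. Thick ascending limb and distal convoluted tubule shared clusters, so they were joined as distal tubule. Clusters with a proximal tubule signal over 0.25 of the proximal tubule level, led by cell cycle genes or without a marker of their own stayed unnamed. The first 2 of these rules were set after clusters had been seen. The embedding was also recalculated at fixed precision after first results had been seen, so that it repeats exactly, and this changed the call counts of several classes.

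Cells are not replicates, so UMIs were summed per library and class. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, edgeR's low count filter by group, and Benjamini-Hochberg adjustment within a class at 0.05. Libraries with at least 20 cells of a class entered its test. All fold changes are log2 values of FMT over saline, with their standard error (SE), and levels are CPM values of the class's UMIs. Numbers of cells per class were tested with the same method, with the kept cells as library size, and their shares with two-sided exact permutation tests. Preset gene lists with at least 5 members past the filter were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Effects in pairs of classes were compared with an interaction term and the mouse as a block, a test added after results were seen. Apart from those of camera, p-values measure the spread between these 5 mice. Camera sets list members against the other genes of a class. At the preset correlation it assumes how list members vary together and does not take this from the mice. With 2 against 3 mice the smallest exact p is 0.1, and counts were not compared with other splits of the mice.

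The groups, tests, gene lists, filters and the rule for named genes were set before the data were examined. The rule took, in each class, up to 10 called genes per direction by fold change with a mean of at least 30 CPM and no overlap between groups, up to 4 called members of each preset list, and, where fewer than 5 genes were called, the 5 smallest p-values per direction, given as values. Predicted gene models were left out of the first part. A preset set of immune and injury genes was also read in every class where its members passed the filter. Genes named outside this rule were chosen after their values were seen. Library pairs were compared for duplicates with a chi-square statistic per gene, which was at least 67.5 in every pair, so all 5 counted as separate. The tests were tested on simulated data, drawn from the fitted means and gene-wise dispersions without a group difference, into which known changes were set. At a true fold of 2 the proximal tubule test recovered 68.7% of changed genes and the B cell test 52.2%. Of all calls in these simulations 12.9% and 14.3% were false, more than the nominal level. They were 18 and 17 false calls in a single simulation per class, where the data gave 13 and 7 calls. The false share with few true changes was not simulated and could be larger. The neutrophil test recovered 11.9% at that fold, with 5.08% of calls false. Cell numbers were simulated with a fixed dispersion of 0.1 instead. Tripling the expected number of T cells in FMT mice was called in 32.5% of 40 simulations. The other classes were not lowered to match, so the T cell share itself was less than tripled.

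Alternatives covered scaling, DESeq2 1.42.0 in place of edgeR, filters on genes and cells, doublet removal, cluster resolution, genes of other classes, equal numbers of cells, adjustment over all classes, a block on the replicate number and leaving out each mouse. Sums without each gene's highest cell (trimmed sums), removal of immune cells with over 1% proximal tubule UMIs, splits of the proximal tubule clusters and an interferon-high cluster counted as proximal tubule were added after the data had been seen. Free RNA from lysed cells enters all droplets, and no correction for it was applied. Proportions of single libraries carry 95% exact binomial intervals, which cover counting error alone. Leaving out a saline mouse leaves 1 library in that group, so such a fit takes its spread from the FMT mice alone.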

Results

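The data comprised droplet single-cell RNA profiles of kidney cells from mice with pristane-induced lupus. Saline-treated mice (n = 2) were compared with mice given FMT from MRL/MpJ donors (n = 3). The series title names inosine from the microbiota, B cell differentiation and B cell migration, and the comparison asks how renal cells differ after the transplant. Saline mice 1 and 2 gave 25661559 and 23014001 UMIs, and FMT mice 1 to 3 gave 45309178, 28423576 and 15333445. After filtering, 5022 and 3187 cells of the saline mice and 5993, 4713 and 2793 cells of the FMT mice were used, with a median of 3265 to 4927 UMIs per cell.

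The kidney cells were mostly proximal tubule cells, which reabsorb most of the filtrate, together with distal tubule and acid-base regulating intercalated cells, B cells, T cells, monocytes and neutrophils. Proximal tubule cells made up 45.0% ± 1.09 of cells in saline mice (SD, n = 2) and 59.5% ± 0.82 in FMT mice (SD, n = 3), with no overlap between groups. All immune classes together made up 41.0% ± 5.02 against 29.0% ± 3.62. B cells were 13.6% ± 0.278 against 9.31% ± 2.08 of all cells, but 33.3% ± 3.40 against 31.9% ± 4.16 of immune cells. Natural killer and innate lymphoid cells were 0.309% ± 0.126 against 0.718% ± 0.202 of all cells.

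No class passed the test of cell numbers in edgeR. The log2 ratio was 0.40 ± 0.28 (SE) for proximal tubule cells with an edgeR adjusted p of 0.665, −0.54 ± 0.33 for B cells with 0.665, and 1.19 ± 0.46 for natural killer and innate lymphoid cells with 0.289. The 2-sided exact permutation p was 0.1 for proximal tubule cells, monocytes, natural killer and innate lymphoid cells and the immune total, the smallest that 2 against 3 mice allow, and 0.2 for B cells. Monocytes were 15.2% of cells in saline mouse 1 (95% exact interval 14.2 to 16.2) and 4.49% in saline mouse 2 (3.79 to 5.26), against 2.58% to 3.40% in FMT mice. Their log2 ratio was −1.68 ± 0.56 with an edgeR adjusted p of 0.289. It was −0.55 without saline mouse 1 and −2.31 without saline mouse 2, in fits that leave 1 saline mouse. Shares depend on how cells were isolated as well as on the tissue.

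**Figure D1:**
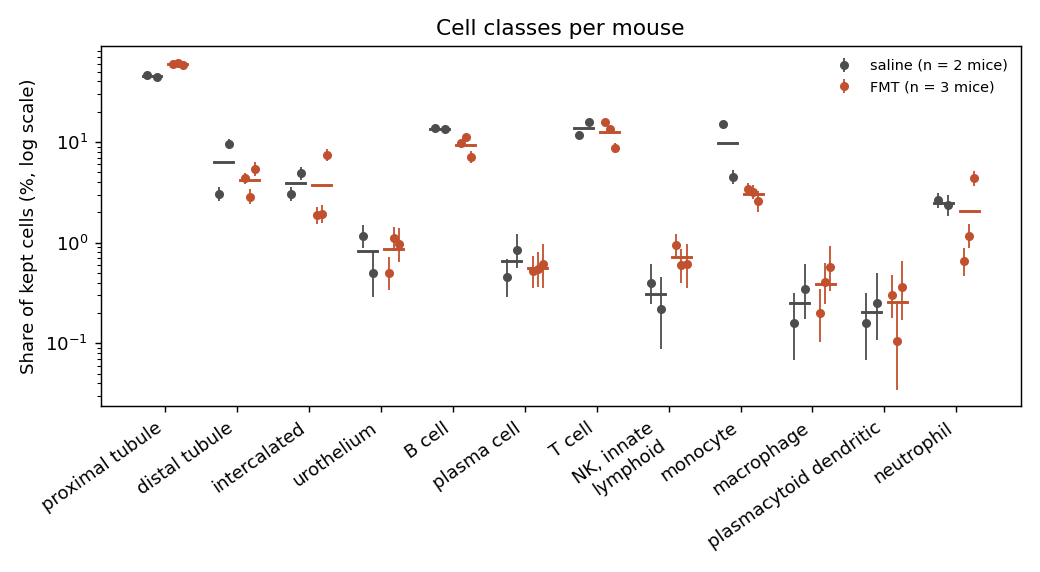
Share of kept cells in each named class on a log scale, with 1 point per mouse, 95% exact binomial intervals and a line at the group mean. Proximal tubule cells lie at 44.3% and 45.8% in saline mice and at 58.7% to 60.4% in FMT mice.

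For plasma cells, the antibody-secreting end stage of B cell differentiation, no difference in their share of the B lineage was shown. The smallest possible exact p is 0.1, so the test could not show that the shares are alike either. The share was 4.59% ± 1.94 in saline mice (SD, n = 2) and 5.90% ± 1.78 in FMT mice (SD, n = 3). The difference of 1.31 percentage points was within the spread between mice (exact permutation p = 0.6). It was −0.06 without saline mouse 1, 2.68 without saline mouse 2 and 0.289 without FMT mouse 3.

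B cells differed between the groups in few genes, most of them lower in FMT mice. This direction turned without FMT mouse 2, where 16 of 19 calls were higher in FMT. Zfp36l2, which encodes a protein that promotes decay of AU-rich mRNA, fell by 1.43 on the log2 scale (SE 0.172), from 468 ± 25.8 to 175 ± 38.1 CPM (SD, n = 2 and 3). Sesn1 and Ddit4, both inhibitors of the growth kinase complex mTORC1, fell by 1.33 ± 0.181 and by 2.03 ± 0.306. Fkbp5, a co-chaperone of the glucocorticoid receptor and a standard target of it, fell by 1.69 ± 0.286, from 63.0 ± 12.6 to 20.7 ± 8.32 CPM. Id3, an inhibitor of E protein transcription factors that steer B cell development, rose by 0.89 ± 0.14, from 189.8 ± 8.19 to 352 ± 15.2 CPM.

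The edgeR test called 7 of 8651 genes in B cells, 1 higher and 6 lower in FMT, where 511 had an unadjusted p under 0.05. Adjusted p was 0.00446 for Zfp36l2 (ENSMUSG00000045817, chromosome 17, 84183931 to 84187947), 0.00915 for Sesn1 (ENSMUSG00000038332, chromosome 10, 41809935 to 41908424), 0.0197 for Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), 0.0377 for Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) and 0.0223 for Id3 (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755). The remaining calls, Ppp1r21 and Dennd4a, fell by 1.42 ± 0.217 and 1.24 ± 0.20. All 7 genes had no overlap between the groups' libraries. The count was 14 without saline mouse 1, 16 without saline mouse 2, 2 without FMT mouse 1, 19 without FMT mouse 2 and 4 without FMT mouse 3. Zfp36l2 kept its call under all 21 alternatives and Sesn1 under 20. Ddit4 lost its call without saline mouse 1, FMT mouse 1 or FMT mouse 2, and Fkbp5 without those or FMT mouse 3. Id3 lost its call without any 1 of the FMT mice, Dennd4a without any of these or saline mouse 1, Ppp1r21 without saline mouse 2 or FMT mouse 3, and Sesn1 without FMT mouse 1.

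Genes of antigen presentation and of differentiation in B cells moved little. The 11 measured MHC class II genes, which present peptides to T cells, were all higher in FMT by a median of 0.14, with 0 calls over all genes and 0 adjusted over the list alone. The camera adjusted p was 0.00732, and the adjusted p was 0.654 with an estimated correlation. Of 18 plasma cell differentiation genes, 14 were higher by a median of 0.13 (camera adjusted p = 0.038, adjusted p = 0.654 with an estimated correlation). Immediate early genes, which answer acute signals, were higher for 17 of 19 members by a median of 0.53 (camera adjusted p = 0.00404, adjusted p = 0.654 with an estimated correlation). Their mean level was higher than in both saline mice in FMT mice 1 and 3, at 8.06 and 8.15 log2 CPM, and lower in FMT mouse 2, at 6.42, against 6.93 and 7.08. Interferon response genes were higher for 25 of 35 members by a median of 0.18 (camera adjusted p = 0.03, adjusted p = 0.654 with an estimated correlation), and 1 was called higher when adjusted over the list alone. Proximal tubule transcripts, foreign to B cells, were higher for 12 of 17 genes by a median of 0.21. The migration genes Cxcr5, Cxcr4 and Ccr7 were −0.48, −0.53 and −0.41, with edgeR adjusted p of 0.826, 0.922 and 0.902. The preset test put 11 of 25 lists past the threshold in B cells, 3 without saline mouse 1 and 7 without FMT mouse 1, and the test with an estimated correlation put 0.

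Genes of purine and inosine metabolism did not pass in any class. In B cells 12 of 22 members were higher by a median of 0.06 (camera adjusted p = 0.427), in T cells 17 of 26 by 0.12 (0.160) and in proximal tubule cells 14 of 25 by 0.09 (0.376). A single member was called over all genes in any class, Aprt, an adenine salvage enzyme, which fell in neutrophils from 302 ± 132.8 to 95.6 ± 26.7 CPM (SD, n = 2 and 3; edgeR adjusted p = 0.0264). Its call was lost without saline mouse 1 or any 1 of the FMT mice.

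T cells shared the lower Ddit4 of B cells. Ddit4 fell by 1.62 ± 0.225 on the log2 scale, from 88.6 ± 11.7 to 31.2 ± 12.0 CPM (SD, n = 2 and 3). Gpr65, a receptor that senses extracellular acid, fell by 1.54 ± 0.186, from 121.8 ± 25.3 to 44.1 ± 10.4 CPM (ENSMUSG00000021886, chromosome 12, 98268635 to 98276644). Naive and resting T cell genes, which mark cells that recirculate without activation, were higher for 12 of 15 members by a median of 0.34, and cytotoxic effector genes for 16 of 22 by 0.35, but with an estimated correlation the adjusted p was 0.631 for both lists. A cluster with Lef1, Tcf7 and Il7r among its leading genes made up 24.1% and 21.9% of T cells in saline mice and 38.9%, 35.7% and 32.4% in FMT mice (exact permutation p = 0.1, adjusted p = 0.15).

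Without FMT mouse 2, 5 of 8 calls in T cells were higher in FMT. With all mice, 3 of 9335 genes were called, all lower, where 555 had an unadjusted p under 0.05. The edgeR adjusted p was 0.00152 for Gpr65 and 0.0075 for Ddit4, and the third gene, Serpina3f, a protease inhibitor named after its values were seen, fell by 2.49 ± 0.34 (adjusted p = 0.00306). Genes short of the threshold included the apoptosis gene Bbc3 at −1.04 and Serinc3 at −0.84 (edgeR adjusted p = 0.0704 each), the chemokine receptor Ccr2 at −0.87 (0.0971) and, among higher genes, Fam101b at 0.72 (0.123) and Cd9 at 0.79 (0.15). The count was 15 without saline mouse 1 or saline mouse 2, 13 without FMT mouse 1 and 8 without FMT mouse 2, and Ddit4 lost its call without saline mouse 2. The naive list had a camera adjusted p of 5.47e-06 and the cytotoxic list one of 0.00522. Adjusted over the list alone, 5 naive genes were higher, and 2 cytotoxic genes were higher and 1 lower. Foreign proximal tubule genes were higher for 13 of 16 members by a median of 0.37, and mitochondrial genome genes lower for 12 of 13 by −0.53. The preset test put 4 of 24 lists past the threshold, 7 without saline mouse 1 and 7 without FMT mouse 2, and 0 passed with an estimated correlation.

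In the edgeR test, proximal tubule cells differed between the groups in few genes, all but 1 of them lower in FMT mice. Calls by DESeq2 were less one-sided, with 33 higher and 55 lower. Cyp24a1, the enzyme that inactivates vitamin D hormone, fell by 1.84 ± 0.227, from 203.7 ± 53.4 to 56.8 ± 14.0 CPM (SD, n = 2 and 3). Gadd45g, a stress-induced growth arrest gene, fell by 2.51 ± 0.301, from 165 ± 89.7 to 29.1 ± 1.32 CPM. Ccnd1, the cyclin that drives entry into the cell cycle, fell by 1.78 ± 0.219, and Tob2, an antiproliferative gene, by 1.53 ± 0.177. The stress-responsive kinase Nuak2, the potassium channel gene Kcnk5 and the DNA-binding gene Nabp1 fell by 1.65 ± 0.209, 1.14 ± 0.147 and 1.02 ± 0.129.

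The test called 13 of 11734 genes in proximal tubule cells, 1 higher and 12 lower, where 1300 had an unadjusted p under 0.05. The edgeR adjusted p was 0.0426 for Gadd45g (ENSMUSG00000021453, chromosome 13, 51846678 to 51848468) and 0.0184 for Cyp24a1 (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145) and the other genes named above. The gene that rose, Lpar6, a lysophosphatidic acid receptor, changed by 0.92 ± 0.14 and kept its call in 10 of 23 alternatives, losing it without saline mouse 1, saline mouse 2, FMT mouse 2 or FMT mouse 3. Wfdc15b and Defb1, which are also leading genes of the distal tubule cluster, fell by 1.84 each and lost their calls without saline mouse 1 or saline mouse 2. These 3 genes were named after their values were seen. The count was 3 without saline mouse 1 and 34 without FMT mouse 1, and DESeq2 called 88. Without saline mouse 1 the calls of Cyp24a1, Ccnd1, Nuak2, Tob2, Kcnk5 and Nabp1 were lost, without saline mouse 2 those of Ccnd1, Nuak2, Kcnk5 and Nabp1, and without FMT mouse 3 those of Nuak2, Nabp1 and Gadd45g. Gadd45g was also lost without FMT mouse 1.

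Immune and injury lists passed the preset test as lower in FMT proximal tubule cells, but none of them passed with an estimated correlation. Interferon response genes were lower for 24 of 36 members by a median of −0.23, MHC class II genes for 9 of 10 by −0.77, migration and chemokine genes for 9 of 12 by −0.71, and tubular injury genes for 17 of 25 by −0.44. The camera adjusted p was 0.00619, 0.00424, 0.0241 and 0.0075, and with an estimated correlation the adjusted p was 0.677 for interferon and 0.631 for the other lists. Adjusted over the list alone, 3 genes were lower in each of the first 3 lists and 0 in the injury list. In the same cells neutrophil transcripts were lower for 8 of 8 genes by a median of −1.81 and B cell transcripts for 5 of 5 by −1.09 (adjusted p = 0.631 each with an estimated correlation). The injury markers Lcn2 and C3 were −2.75 and −1.55, with edgeR adjusted p of 0.408 and 0.313. Oxidative phosphorylation genes were higher for 45 of 57 members by a median of 0.11 (camera adjusted p = 0.00407, adjusted p = 0.631 with an estimated correlation). Of 28 lists, 12 passed the preset test and 0 passed with an estimated correlation.

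**Figure D2:**
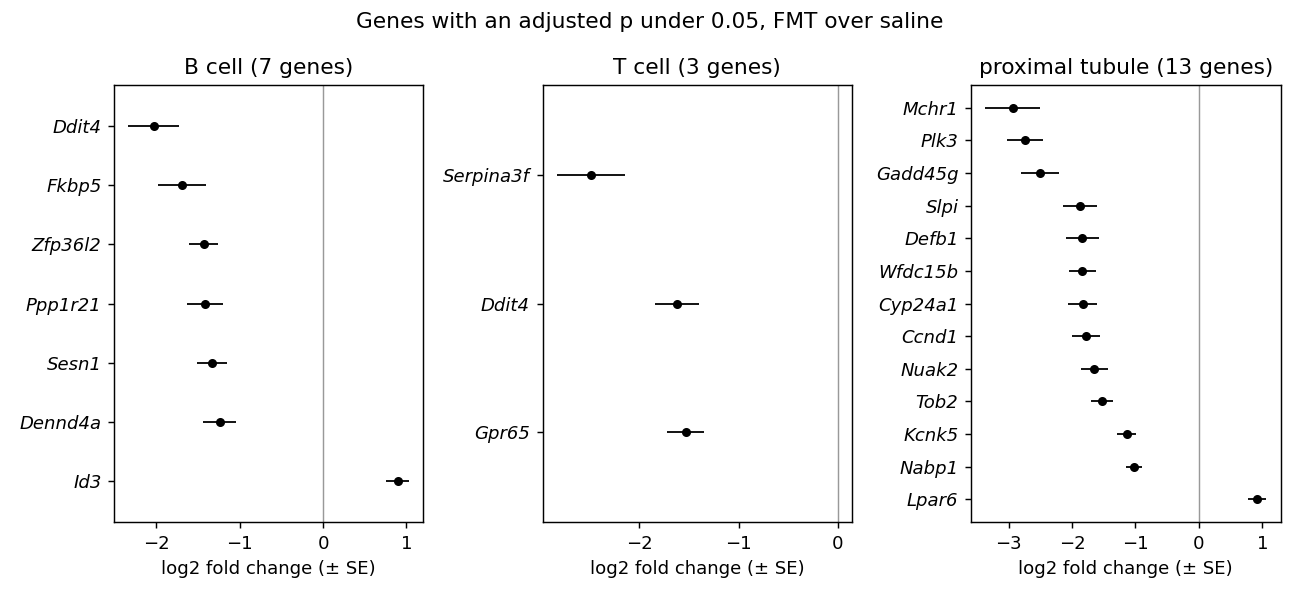
Log2 fold change of FMT over saline with its SE for every gene called in B cells, T cells and proximal tubule cells. All but Id3 in B cells and Lpar6 in proximal tubule cells lie below 0, and values run from −2.94 to 0.92.

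Distal tubule cells fine-tune salt excretion, and this class joins thick ascending limb and distal convoluted tubule cells. A cluster led by Umod and Slc12a1 held 6 of its 154 and 31 of its 305 cells in the saline mice. In the FMT mice that cluster held 34 of 261, 9 of 135 and 29 of 150. The class differed between the groups in genes of both directions. Rcan1, an inhibitor of calcineurin, fell by 1.81 ± 0.283, and Neat1, a long non-coding RNA that scaffolds nuclear paraspeckles, by 1.20 ± 0.191, from 1095 ± 44.7 to 474 ± 130 CPM (SD, n = 2 and 3). The kinase gene Pim3 fell by 1.01 ± 0.173 and Nabp1 by 1.03 ± 0.184. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 1.80 ± 0.313, from 14.5 ± 5.14 to 47.7 ± 10.4 CPM, and Cited2, a transcriptional co-regulator, by 1.00 ± 0.20.

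In distal tubule cells 15 of 8431 genes were called, 7 higher and 8 lower, where 408 had an unadjusted p under 0.05. The edgeR adjusted p was 0.000951 for Rcan1 (ENSMUSG00000022951, chromosome 16, 92391953 to 92470867) and Neat1 (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478), 0.00263 for Pim3, 0.0037 for Nabp1, 0.00278 for Angptl4 and 0.0121 for Cited2. Akr1c21, a marker of proximal tubule RNA, rose by 2.53 ± 0.444. Proximal tubule marker genes were higher for 11 of 12 members by a median of 0.97 (camera adjusted p = 1.31e-11, adjusted p = 0.223 with an estimated correlation), and 5 were higher when adjusted over the list alone. Fatty acid oxidation genes, many of them abundant in proximal tubule cells, were higher for 26 of 31 members by 0.27 (camera adjusted p = 8.57e-07, adjusted p = 0.176 with an estimated correlation). MHC class I genes were lower for 8 of 10 members by −0.32 (camera adjusted p = 0.00909, adjusted p = 0.582 with an estimated correlation). The count was 52 without FMT mouse 2, 39 higher and 13 lower in FMT. Angptl4 lost its call without saline mouse 2, Cited2 without saline mouse 1 or FMT mouse 1, and Akr1c21 without any 1 of saline mouse 1, saline mouse 2 and FMT mouse 1. Of 20 lists, 7 passed the preset test and 0 passed with an estimated correlation.

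No gene was called in intercalated cells by edgeR, where 110 of 4345 genes had an unadjusted p under 0.05, or by DESeq2, which also called 0. The genes with the smallest p were Gsta2, a glutathione transferase, at −1.30 (edgeR adjusted p = 0.538) and Rnf187 at 1.03 (0.999). Without saline mouse 1, 6 genes were called, and without saline mouse 2, 1. Proximal tubule marker genes were lower here for 14 of 15 members by a median of −0.78, the opposite sign to distal tubule cells (camera adjusted p = 3.24e-06, adjusted p = 0.528 with an estimated correlation). The mitochondrial genome list passed as lower while its median was 0.08 and its mean −0.02. Of 15 lists, 5 passed the preset test, 1 without saline mouse 2 and 3 without FMT mouse 3, and 0 passed with an estimated correlation.

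The monocyte class of FMT mice carried more RNA of Ccl5, a chemokine that attracts T cells. Ccl5 is also among the leading genes of the natural killer and innate lymphoid cluster. Ccl5 rose by 2.60 ± 0.295, from 75.1 ± 0.531 to 454.6 ± 102.5 CPM (SD, n = 2 and 3). In the FMT mice, 54.2% of its UMIs came from the highest cell of each library. Interferon response genes were higher for 37 of 39 members by a median of 0.66, and ribosomal protein genes were lower for 75 of 77 by −0.23, but with an estimated correlation the adjusted p was 0.735 for both lists. Fkbp5, the chemokine receptor Cxcr4 and the clock gene Per1 were −1.93, −1.68 and −1.75, with an edgeR adjusted p of 0.361 each, and among higher genes Acot1 was 1.64 (0.361) and Gdf15 3.05 (0.773). In the clustering without doublet removal, 1.71% and 12.6% of these monocytes in saline mice and 8.33%, 21.2% and 34.7% in FMT mice fell into a cluster with Fn1, F13a1 and Ccr2 among its leading genes, compared after results were seen.

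Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was the single call among 7109 genes, with an edgeR adjusted p of 0.0199, where 324 had an unadjusted p under 0.05. With genes of other classes left out, 0 monocyte genes were called. That setting drops genes over 10 times lower than in their highest class before the test. It can remove Ccl5, a leading gene of the natural killer and innate lymphoid cluster, so the 0 is no test of this call. The Ccl5 call was kept in 11 of 20 alternatives, but not with no doublets removed, 2 times the doublets removed or Leiden resolution 0.5. It was lost without saline mouse 1, FMT mouse 2 or FMT mouse 3, and with its highest cell in each library left out its log2 fold change was 2.27 with an edgeR adjusted p of 0.792. The count was 0 without saline mouse 1 or FMT mouse 2, 37 without saline mouse 2, 3 without FMT mouse 1 and 2 without FMT mouse 3. The interferon list had a camera adjusted p of 1.26e-08 and the ribosomal list one of 7.2e-12. No interferon gene was called over all genes or adjusted over the list alone. Foreign proximal tubule genes were higher for 15 of 17 members by a median of 0.72. The red cell list passed as lower although its median was 0.93. Of 27 lists, 10 passed the preset test, 0 passed with an estimated correlation, and fry called the migration and chemokine list higher (fry adjusted p = 0.0356, adjusted p = 0.735 with an estimated correlation).

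The neutrophil class of saline mice contained RNA of dividing granulocyte precursors that was nearly missing from that class in FMT mice. Elane and Mpo, granule enzymes made in precursors, were at 480.2 ± 6.99 and 99.98 ± 39.5 CPM in saline mice (SD, n = 2) and at 0 in FMT mice (n = 3). Against a floor of 3 counts over the FMT group they were at least 115-fold and at least 24.0-fold lower. The proliferation genes Top2a and Mki67 fell from 76.3 ± 14.9 to 0.873 ± 1.51 CPM and from 90.1 ± 34.4 to 6.11 ± 10.6 CPM. A gene can pass the low count filter through its higher group alone, which favours a uniform direction within a list. All 12 measured cell cycle genes were lower, 6 of them called over all genes and 12 adjusted over the list alone, with an adjusted p of 0.132 for the list with an estimated correlation. Few cells carried much of this RNA. Cell cycle UMIs per cell were 19.4 and 17.1 in saline mice and 7.38, 7.05 and 8.11 in FMT mice, and 7.73 and 8.26 against 7.38, 7.05 and 6.98 outside cells with at least 100 of them. In saline mouse 2 a single cell held 272 of 273 UMIs of the granule genes Elane, Mpo and Prtn3, in saline mouse 1 a single cell held 379 of 578. Such RNA was also found in cells of the monocyte class, with 11 and 81 UMIs in saline mice and 32, 13 and 76 in FMT mice.

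In neutrophils 26 of 3121 genes were called, 2 higher and 24 lower, where 356 had an unadjusted p under 0.05. The edgeR adjusted p was 8.14e-07 for Elane (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), 0.000727 for Mpo and Top2a and 0.0264 for Mki67. For 9 of the 26 genes over 50% of UMIs in the higher group came from the highest cell of each library, and without those cells 11 of the 26 were still above the low count filter and 4 were called. The count was 101 without saline mouse 2 and 15 without FMT mouse 3, and Top2a and Mki67 lost their calls without saline mouse 1. The cell cycle list had a camera adjusted p of 3.64e-13 and a fry adjusted p of 0.0475. Interferon response genes were higher for 30 of 35 members by a median of 0.51 (camera adjusted p = 1.63e-06, adjusted p = 0.782 with an estimated correlation), and ribosomal protein genes lower for 77 of 77 (adjusted p = 0.780 with an estimated correlation). Proximal tubule marker genes were higher for 14 of 15 members by 0.68, with a fry adjusted p of 0.0475, and the adjusted p was 0.132 with an estimated correlation. Of the 2 genes that rose, Timp3, an inhibitor of matrix proteases, changed by 2.64 ± 0.546 and the proximal tubule gene Akr1c21 by 1.78 ± 0.384. Timp3 lost its call without saline mouse 1, FMT mouse 1 or FMT mouse 3, and Akr1c21 without saline mouse 1 or any 1 of the FMT mice. Of 24 lists, 7 passed the preset test and 0 passed with an estimated correlation.

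Plasma cells were compared between saline mice (n = 2) and FMT mice 1 and 2, since FMT mouse 3 held 17. The called genes included genes of cell division and of proximal tubule cells. Cdk1, the mitotic kinase, was at 0 in saline mice and at 79.6 ± 8.16 CPM (SD, n = 2) in FMT mice, at least 11.3-fold higher against a floor of 3 counts over the saline group. Ube2c, a mitotic ubiquitin conjugating enzyme, rose from 6.76 ± 9.56 to 303.1 ± 56.5 CPM. The stress and hypoxia gene Ndrg1 rose by 3.03 ± 0.355, from 29.7 ± 3.76 to 250.8 ± 7.62 CPM, and is also among the leading genes of a proximal tubule cluster. Gpx3, a secreted peroxidase of proximal tubule cells, rose by 3.24 ± 0.49. It was −0.11 when cells with over 1% proximal tubule UMIs were left out, which reduced the calls in plasma cells to 4. Gpx3 is itself on the list that picks those cells, so its own drop was partly set in advance. The plasma cell regulators Irf4 and Prdm1 were −1.01 and −1.27, with edgeR adjusted p of 0.159 and 0.276.

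In plasma cells 18 of 2973 genes were called, all higher, where 300 had an unadjusted p under 0.05. The edgeR adjusted p was 0.0311 for Cdk1, 0.012 for Ube2c and Ndrg1 and 0.0304 for Gpx3. Cell cycle genes were higher for 13 of 13 members, 11 of them adjusted over the list alone, and foreign proximal tubule genes for 15 of 15, 14 of them adjusted over the list alone. As in neutrophils, the low count filter can favour such a uniform direction. A single cell held 386 of 824 cell cycle UMIs in FMT mouse 1 and 365 of 788 in FMT mouse 2. The untested FMT mouse 3 had 122 in 17 cells, or 7.18 per cell, and saline mice had 195 in 23 cells and 158 in 27 cells, or 8.48 and 5.85 per cell. Cells with over 1% proximal tubule UMIs were 0% and 7.41% in saline mice and 19.4%, 11.5% and 0% in FMT mice. Without each gene's highest cell, 9 of the 18 were still above the low count filter, and 2 were called, Ube2c and Ndrg1. Genes of plasma cell differentiation were lower for 20 of 24 members by a median of −0.29 (camera adjusted p = 0.000279), 2 of them adjusted over the list alone. With an estimated correlation the adjusted p was 0.475 for these 3 lists. Leaving out any 1 of these mice leaves 1 library in a group, with the spread taken from the other group alone. The count rose in each such fit. Cdk1 lost its call without FMT mouse 1. Of 22 lists, 12 passed the preset test and 0 passed with an estimated correlation.

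In sums over all cells, which mix expression with cell shares, no gene passed in edgeR. Among 14259 genes 2037 had an unadjusted p under 0.05, and DESeq2 called 445. Without saline mouse 2, edgeR called 140. The smallest p-values belonged to Gadd45g at −1.81 (edgeR adjusted p = 0.126), Serinc3 at −1.03 (0.174), the lipolysis inhibitor gene G0s2 at 1.36 (0.174) and Id1 at 1.12 (0.174). Fatty acid oxidation genes were higher for 32 of 35 members by a median of 0.42, and inflammation genes lower for 29 of 35 by −0.49, with more proximal tubule and fewer immune cells in FMT mice. Of 29 lists 11 passed the preset test and 0 passed with an estimated correlation. T cell activation genes were lower for 23 of 26 members by −0.39, with a fry adjusted p of 0.0133 (adjusted p = 0.592 with an estimated correlation).

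Some genes had the same sign in many classes, although the classes came from the same mice and are not independent. Fkbp5 was lower in 7 of 7 classes that measured it and was called in B cells. Ddit4 was lower in 6 of 6 and was called in B and T cells. In distal tubule cells it was −0.11 with overlapping groups, and in proximal tubule cells it lay between 0.56 and 1.62 CPM. Rcan1 was lower in 5 of 5, Neat1 lower in 7 of 8 and Id3 higher in 7 of 8. Akr1c21 and Spp2, leading genes of proximal tubule clusters, and Sord were higher in 8 of 8. Fmo1 was higher in 7 of 7, and Gnb2l1 lower in 8 of 8.

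**Figure D3:**
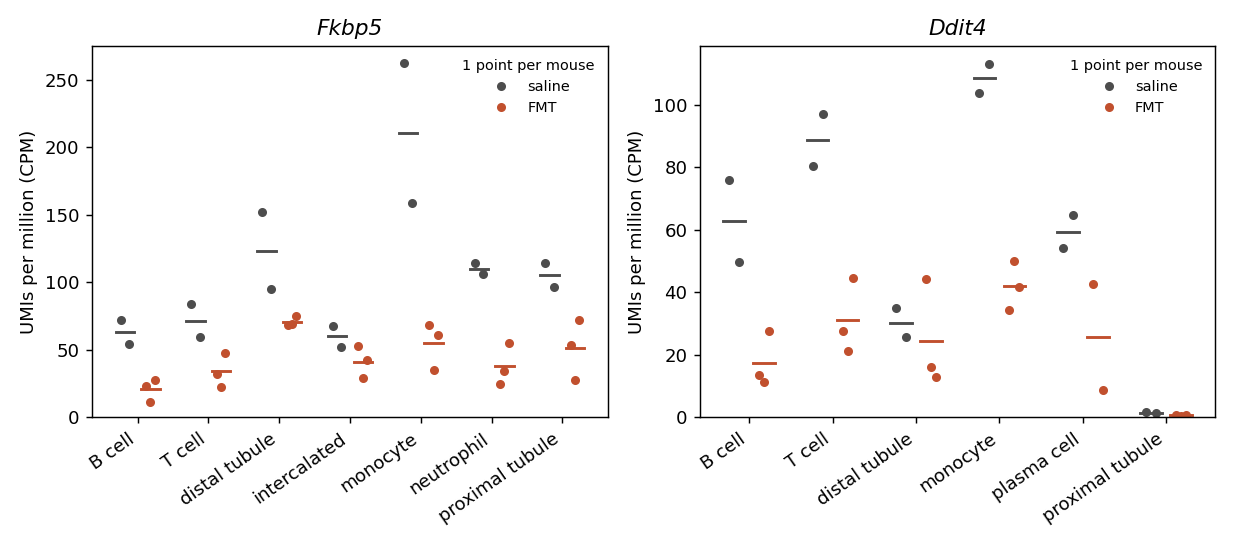
CPM of Fkbp5 and Ddit4 in each class that measured them, with 1 point per mouse and a line at the group mean. Fkbp5 means are lower in FMT in 7 of 7 classes, and Ddit4 means in 6 of 6.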

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

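The tests behind this part compared fold changes between cell classes of the same mice with an interaction term, for genes called in at least 1 of the classes. These tests were chosen after results were seen, and no explanation of the differences was tested.

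Of 19 genes called in distal or proximal tubule cells and measured in both, 8 differed between the classes, among 31 that differed of 8106 tested. The log2 fold change in distal minus proximal tubule cells was 1.40 for Ccnd1 and 1.09 for Tob2, called in proximal tubule cells alone. It was 2.05 for Akr1c21 and 2.62 for Angptl4, called in distal tubule cells alone. Outside the rule for named genes it was 2.12 for Fmo1, 1.70 for Wfdc15b, 1.67 for Cda and 1.67 for Defb1.

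B cells and proximal tubule cells also differed. The log2 fold change in B cells minus that in proximal tubule cells was 1.38 for Nuak2, 2.52 for Gadd45g, 1.37 for Tob2, −1.42 for Sesn1, −2.06 for Zfp36l2 and −1.15 for Ppp1r21. In T cells minus proximal tubule cells it was 2.56 for Gadd45g and 1.40 for Tob2. Outside the rule Plk3 differed by 3.05 in B cells and 2.85 in T cells, and Lpar6 by −1.23 in T cells. In T cells minus B cells it was 1.20 for Sesn1, the 1 gene of 9 called in either lymphocyte class and measured in both that differed. Zfp36l2 and Sesn1 fell in B cells and were 0.64 and 0.12 in proximal tubule cells, where neither was called. The genes outside the rule were chosen after their values were seen.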

How the results depend on the processing

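Of the tests in this part, the trimmed sums, the removal of cells with proximal tubule RNA, the splits of proximal tubule clusters and the interferon-high cluster counted as proximal tubule were chosen after results were seen. Counts of called genes were unstable. The sets of cells changed too when the clustering was recalculated at fixed precision after first results had been seen, and call counts moved with it. Named genes and class shares kept their label, called or not called, in 4159 comparisons with an alternative. They were weaker, with a call lost, in 339, stronger in 101 and reversed in 2. Most of them were not called in the main test, and for these a change of sign counted only with a call. With DESeq2, 27 of the 83 called genes lost their call. Counts stayed within 1.5 times of the reported value, or the plasma cell share difference within the spread between mice, in 182 comparisons, and moved further in 103. In simulations with many set changes 12.9% of proximal tubule calls and 14.3% of B cell calls were false. The false share with few true changes was not simulated, so single calls are weak, above all near the threshold. The cause of each move below was not tested.

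Without the low count filter the calls were 50 in B cells, 59 in T cells, 44 in distal tubule, 2 in intercalated cells, 60 in monocytes, 107 in neutrophils, 202 in plasma cells, 338 in proximal tubule and 13 over all cells. DESeq2 called 10 in T cells, 9 in distal tubule, 5 in monocytes, 12 in neutrophils, 28 in plasma cells, 88 in proximal tubule and 445 over all cells. With the replicate number as a block, which is not a pairing in the labels, they were 10 in T cells, 3 in distal tubule, 14 in intercalated cells, 0 in monocytes, 61 in neutrophils, 31 in proximal tubule and 1 over all cells, and lists past the threshold were 7 in B cells, 8 in T cells and 17 over all cells.

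With no doublets removed the calls were 5 in T cells, 36 in distal tubule, 0 in monocytes and 9 in plasma cells. With 2 times the doublets removed they were 4 in monocytes and 1 in neutrophils, and H2-Aa in monocytes turned to 1.93. Leiden resolution 0.5 gave 3 in B cells and 0 in monocytes. Equal cells per library gave 3 in B cells, 7 in T cells, 0 in neutrophils and 9 in plasma cells. Without genes of other classes they were 6 in T cells, 0 in monocytes and 10 in plasma cells. This setting drops genes over 10 times lower than in their highest class before the test, so a lower count can be set in advance. Without cells holding proximal tubule RNA they were 3 in monocytes and 4 in plasma cells. Gpx3, which is on the list that picks those cells, turned to −0.11 in plasma cells. Trimmed sums gave 0 in monocytes, 4 in neutrophils and 2 in plasma cells. Adjusted over all classes they were 6 in T cells, 14 in neutrophils and 4 in plasma cells. Proximal tubule calls were 35 in low and 21 in higher mitochondrial clusters.

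Leaving out each mouse gave 2 to 19 calls in B cells, 4 to 15 in T cells, 16 to 52 in distal tubule, 0 to 6 in intercalated cells, 0 to 37 in monocytes, 15 to 101 in neutrophils, 43 to 208 in plasma cells, 3 to 34 in proximal tubule and 0 to 140 over all cells. Classes past the test of cell numbers were 0 to 1. Lists past the threshold were 3 to 10 in B cells, 5 to 7 in T cells and 1 to 6 in intercalated cells. The plasma cell difference ran from −0.06 to 2.68 points and was 0.289 without FMT mouse 3. With an estimated correlation 0 lists passed in any class. With fry 1 passed in monocytes, 3 in neutrophils and 1 over all cells, and 0 elsewhere. RLE scaling moved no count past 1.5 times, but it shifted B cell fold changes by a median of 0.00612 and so hardly differed from TMM. Not run were immunoglobulin isotypes, plasma cells defined by immunoglobulin share, and the plasma cell test with at least 50 cells, with 2 times the doublets removed or without FMT mouse 3. Depth limits the rare classes, with as few as 110162 UMIs per library in neutrophils.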

Other observations

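Among the tests in this part, the prediction for proximal tubule RNA in distal tubule cells was written before its value was seen. All other tests, and the list of genes induced by glucocorticoids, were chosen after results were seen, and the rules for free RNA and for dissociation were tightened after their values were known.

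T cells divided into subsets whose shares did not pass a test between the groups. A cluster with Lef1, Tcf7 and Il7r, genes of resting T cells, among its leading genes made up 24.1% and 21.9% of T cells in saline mice 1 and 2 and 38.9%, 35.7% and 32.4% in FMT mice 1 to 3. A cluster with Il7r and Cxcr6, a receptor of tissue-resident T cells, made up 50.3% and 56.3% against 29.3%, 38.5% and 38.9%. Cd8a and Cd8b1 were among the leading genes of the remaining cluster, at 25.6% and 21.7% against 31.8%, 25.8% and 28.7%. Cxcr6 and Il7r were also leading genes of that cluster, and Cd8b1 also of the cluster with Lef1. These genes therefore do not set the clusters apart as separate cell types. The exact permutation p was 0.1, 0.1 and 0.2 (adjusted p = 0.15, 0.15 and 0.2), and 0.1 is the smallest possible with 2 against 3 mice. The subsets were compared after they had been seen.

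The cell cycle genes in neutrophils and plasma cells may follow a few cells that carried them. The log2 ratio of cell cycle UMIs per cell, FMT over saline, was −1.28 in neutrophils and 1.99 in plasma cells, and −0.16 and 0.51 outside cells with at least 100 of them, which were picked by the same genes. Saline mice held 8 and 2 neutrophil-class cells with at least 100 cell cycle UMIs, FMT mice 0, 0 and 1. The monocyte class held 1 and 2 such cells in saline mice and 0, 0 and 2 in FMT mice. With equal cells per library 0 neutrophil calls were left. This cannot be told apart from the same effect, since a random draw may miss the few neutrophil-class cells.

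Proximal tubule genes in distal tubule cells may reflect proximal tubule RNA in that class, from free RNA or mixed droplets. Of the genes 10 times higher in proximal than distal tubule cells, 88.16% were higher in FMT, with a median of 0.70, although Gpx3 and Slc34a1, picked after their values were seen, were −0.02 and 0.14 in distal tubule cells. Free RNA alike in every class cannot be told apart from RNA of mixed droplets. The same genes had a median of 0.22 in B cells, 0.24 in T cells, 0.93 in monocytes, 0.58 in neutrophils and 2.66 in plasma cells, but −0.41 in intercalated cells, where the groups' levels overlapped. In distal tubule cells of FMT mice, the highest cell of each library held 36.4% of Akr1c21, 49.5% of Cda and 24.2% of Fmo1 UMIs. The median over the 15 distal tubule calls, each in its higher group, was 9.92%. Trimmed sums left 10 of these calls, 3 higher and 7 lower in FMT. Akr1c21, Cda and Fmo1 were picked after their values were seen, so they do not settle the source. No biological explanation was tested.

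Genes induced by glucocorticoids, such as Fkbp5 and Ddit4, had a median below 0 in all tested classes but neutrophils, with 15 of 17 list members lower in proximal tubule cells, 7 of 13 in B cells and 4 of 11 in neutrophils, and with an estimated correlation the smallest adjusted p was 0.164 over all classes and 0.097 within a class. Of the 7 B cell calls, 2 were list members. A few cells did not carry the 7 calls, which were all left in trimmed sums. That result covers no list member outside B cells. Scaling between libraries cannot be told apart, because RLE scaling left 7 calls but shifted fold changes by a median of 0.00612. Lower glucocorticoid levels or another time of collection could give the pattern, a hypothesis the data leave open. List members not seen when the list was written had a median below 0 in 5 of 7 classes, but a smallest adjusted p of 0.439 over all classes, and 0.221 within a class, with an estimated correlation. Longer dissociation of saline kidneys also cannot be told apart, because the immediate early list had a median of 0.53 in B cells but was lowest in FMT mouse 2.

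Clock genes that peak in the evening, a list written after results were seen, were lower in FMT for 8 of 11 members in proximal tubule cells (camera adjusted p = 0.0019 within the class, adjusted p = 0.28 with an estimated correlation) and 7 of 9 in T cells (0.017 and 0.341). The list did not pass in distal tubule cells, with 7 of 11 lower (camera adjusted p = 0.0577), B cells, with 6 of 8 lower (0.623), intercalated cells, with 3 of 6 lower (0.548), or monocytes, with 4 of 5 higher (0.512), and clock genes that peak in the morning did not pass in B, T or proximal tubule cells, the classes with enough of them to test.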
